A study of Homo sapiens with 6 samples.

How the data were processed

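RNA from LX2 cells, an established human hepatic stellate cell line, was measured on 6 one-channel Phalanx microarrays. Per the labels, 3 samples had been treated with Syy and 3 were controls; groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit, amplified to amino allyl RNA and labelled with Cy5. The dose and duration of the treatment, the scanner software, the background method and the target of the scaling are not given in the sources used here. The labels do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

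The deposited values are intensities on a linear scale for 31741 probes. On each array every deposited intensity was a whole number of units, within a tolerance of 0.05 units, times 1 factor, which ran from 0.920 to 1.08 over the arrays. The arrays had therefore been scaled by a single factor each and had not been quantile normalized; the reason for the factors is not given in the sources used here. The lowest deposited value was -10.6, and 1902 probes had a value at or below 0 on at least 1 array. At the upper end, 7 probes reached a common ceiling on at least 1 array. The median deposited intensity was 25.7, 27.4 and 23.1 on the Syy arrays and 24.9, 22.3 and 18.4 on the control arrays, and the upper quartile was 179.6, 200.9 and 185.6 against 168.1, 154.1 and 137.0. No detection flags were used, and the number of arrays limits the precision.

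The design, written before the data were examined, took the values as deposited if the distributions of the arrays matched and quantile normalization otherwise. They did not match: the median difference between Syy and control was 0.03 for probes below 5 on the log2 scale, 0.30 for probes between 8 and 10, and -0.05 above 12. The values used here are therefore log2(value + 16), quantile normalized over the 6 arrays. The pseudocount of 16 was needed because of the values at or below 0. Fold changes are on the log2(value + 16) scale, which understates the change of dim genes.

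Probes were named from the platform annotation, which can be old. Of all probes, 24740 had 1 gene symbol, 977 had several and 6024 were unnamed here. A gene was represented by its probe with the highest mean over the 6 arrays among probes with 1 symbol, which gave 18365 genes, of which 12924 had a single probe. Of these symbols, 16811 are current in the RefSeq table of GRCh38.p14 and 1553 are listed there as older names; the text keeps the platform's symbols. In 2147 genes at least 2 probes lay above the median of all probes. All such probes of a gene gave the same verdict in 1320 of these genes, some were called and some were not in 799, and 28 genes had probes called in opposite directions.

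Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 18365 genes and a threshold of 0.05. No covariate was used. Gene lists were compared with limma's camera at a preset correlation of 0.01, adjusted over the 46 lists with at least 5 measured members. The lists were fixed before the data were examined and cover stellate cell functions, secretion, stress responses, metabolism, the cell cycle and the markers of other cell types; 69 of their 1374 entries could not be placed on the array. Each list was also tested with a correlation estimated from its own residuals and with fry, which asks whether the genes of a list move one way on balance and does not compare the list with other genes. With an estimated correlation camera works with the few residual degrees of freedom that 6 arrays leave. That test therefore had little power here, and failing it does not show that a list was unchanged.

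The genes named in the text follow a rule fixed beforehand. It takes the 10 largest rises and the 10 largest falls among called genes whose Syy values all lie beyond all control values and with at least 1 group mean above the median of all probes. It adds the 4 members with the smallest p in each called list, 10 stellate cell genes whatever their values, and at most 2 members of lists that were not called. The last part was used for the lists of the secretory pathway. Genes named outside the rule are said to have been chosen after their values were seen. Genes on the Y chromosome and XIST were left out.

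The same steps were tested on simulated data for the comparison of Syy with control, over 18365 genes. Of 50 genes raised by 1 on the log2 scale 72% were recovered, and of 50 lowered by 1, 78%. For changes of 0.5 the shares were 16% upwards and 22% downwards. Of 18132 unchanged genes 3 were called. The changed genes were few, came from those above the median of all probes, and had noise drawn separately for each probe. The real comparison called many more genes, so these shares need not hold for it or for dim genes.

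The alternatives set beforehand were median centring, filters on dim probes, another pseudocount, the mean over all probes of a gene, eBayes with a trend and robust estimation, array weights, a replicate block, each sample left out in turn and other list tests. Chosen after seeing the data were the values as deposited, a pseudocount of 1 with values below 0 set to 0, and a fit without Syy replicate 3 and control replicate 2, which held transcripts that read far lower on the other arrays.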

Results

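Gene expression was compared between LX2 cells treated with Syy (3 arrays) and control LX2 cells (3 arrays). LX2 is a line of human hepatic stellate cells, the liver cells that deposit collagen during fibrosis. Syy is a code name for a molecule that the submitters describe as blocking secretion by these cells, and the comparison asks how transcript levels differ in its presence. Spearman correlations of the deposited intensities over all probes were 0.973 to 0.977 between Syy arrays, 0.984 to 0.985 between control arrays and 0.968 to 0.977 between the groups.

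With Syy, 12 of 19 collagens and 16 of 33 other matrix genes rose, 3 of the latter fell, and 13 of 29 genes of the oxidative stress response fell, with HMOX1 8.74-fold lower. The camera tests of these lists passed with a preset correlation between genes but not with an estimated one (adjusted p = 0.329, 0.316 and 0.316). The test with an estimated correlation had little power with 6 arrays. Of 18365 genes, 2017 were higher and 2104 lower at an adjusted p under 0.05 (limma), and 300 of them differed by at least 2-fold, 119 upwards and 181 downwards. The median change of called genes was 0.52 upwards and -0.53 downwards on the log2 scale. In 38.3% of genes the 3 Syy values lay wholly above or below the 3 control values, against 10% expected by chance. The balance of the directions depended on the scaling: 48.9% of the calls were higher here, 60% after median centring (2493 higher, 1659 lower) and 81.1% in the values as deposited (3157 higher, 737 lower). Leaving out a single array, which also lowers power, moved the counts too. Without control replicate 1, 1205 genes were higher and 1153 lower. The counts were 1235 and 1079 without control replicate 2 and 1313 and 1152 without control replicate 3. Without Syy replicate 2, 1265 genes were lower.

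Syy replicate 3 held transcripts associated with the hepatocyte lineage that read far lower on the other arrays. APOA2, an apolipoprotein of the liver, read 14.09 on the normalized log2 scale on that array, against 5.19 and 6.49 on the other Syy arrays and 6.68 to 7.53 on the controls. H19 read 12.16 there and 6.41 to 6.65 elsewhere. DLK1 read 9.04 there and 4.17 to 4.45 elsewhere, and AFP 7.82 there and 6.15 to 7.33 elsewhere. Of 18 hepatocyte markers, 11 were more than 1 log2 unit above the mean of the other Syy arrays in Syy replicate 3. None was so on any control array against the other controls. For Syy replicates 1 and 2 the count was 0 too, but their reference included Syy replicate 3, so a rise there could hardly show. The marker list had a median log2 fold change of 0.61 with an adjusted camera p of 0.0755, and 0.05 without Syy replicate 3 (adjusted p = 0.728); it was called without Syy replicate 1 or 2 (adjusted p = 0.00605 and 0.0253) and with the replicate block (adjusted p = 0.048), but not with an estimated correlation (adjusted p = 0.733). In control replicate 2 GCNT3 read 8.09, against 4.18 to 4.55 elsewhere; 10 genes lay at least 4-fold above both other controls there, fewer than the 12 such genes of Syy replicate 2. These genes were chosen after their values were seen. Without Syy replicate 3 and control replicate 2, a choice made after seeing the data that leaves 2 samples per group, 566 genes were higher and 535 lower, and 32 of the 87 genes taken by the naming rule no longer passed. The log2 fold changes of those 32 were 0.84 to 1.2 times their values over 6 arrays, with adjusted p from 0.0502 to 0.147.

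**Figure D1:**
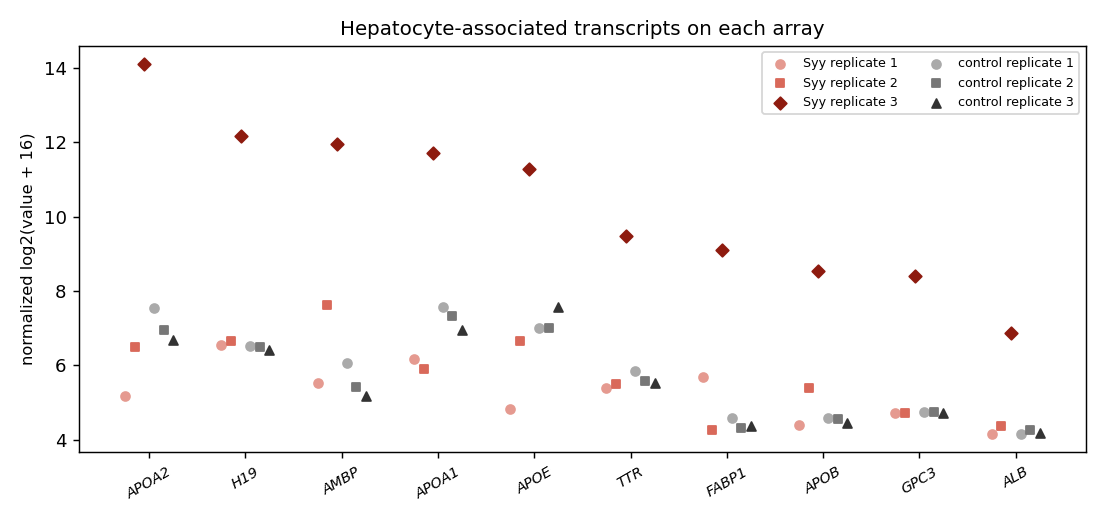
Normalized log2(value + 16) levels of 10 transcripts associated with the hepatocyte lineage, 1 point per array. The dark diamonds of Syy replicate 3 lie above all other arrays, from 6.88 for ALB to 14.09 for APOA2.

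Of the 19 fibrillar and network collagens measured, 12 rose, none fell and 7 did not pass (14 rose adjusted over the list alone), with a median log2 fold change of 0.58 and a camera adjusted p of 6.37e-06 (adjusted p = 0.329 with an estimated correlation). COL5A1 rose 2.76-fold, from 11.95 ± 0.16 to 13.41 ± 0.17 (SD, n = 3 each, on the normalized log2 scale), and both of its probes gave the same change (1.46 and 1.49). COL6A3 rose 2.32-fold, COL4A1, of basement membranes, 2.03-fold and COL7A1 1.60-fold. COL1A1, the main chain of fibrillar collagen in scars, rose by 1.07 ± 0.16 (SE). COL3A1 rose by 0.52, a call that was lost without Syy replicate 1 or 2 or without any 1 control, with adjusted p from 0.0508 to 0.104, and with the replicate block (adjusted p = 0.0772; 0.0134 to 0.104 over all alternatives). COL1A2 lay near the floor of the array and read 0.46 higher without passing (adjusted p = 0.0851; 0.0152 without control replicate 1, in a range of 0.0152 to 0.329 over the alternatives). Without Syy replicate 3 and control replicate 2 the collagen median was 0.63, with an adjusted p of 1.72e-05 and 7 members higher.

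Genes of collagen processing and crosslinking, not all of which encode enzymes, were higher in part. Of 23, 7 rose and 2 fell (10 and 2 adjusted over the list alone). The median was 0.29 and the camera adjusted p 0.0217 (0.337 with an estimated correlation and 0.062 without Syy replicate 1). Of these genes 2 rose and 1 fell without Syy replicate 3 and control replicate 2, and the list stayed called (camera adjusted p = 0.0159). LOX, which crosslinks collagen, rose 2.35-fold and LOXL2 1.77-fold; the prolyl hydroxylase subunits P4HA2 and P4HB rose 1.75-fold and 1.47-fold. LOX had 3 probes, with changes of 1.23, 0.44 and 0.20, the last not called, and the change of the gene ran from 0.623 to 1.524 over the alternatives.

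Among 33 non-collagen matrix proteins, 16 rose, 3 fell and 14 did not pass (17 and 4 adjusted over the list alone), with a median of 0.30 and an adjusted p of 0.000705 (adjusted p = 0.316 with an estimated correlation). The list had 10 higher and 1 lower without Syy replicate 3 and control replicate 2, and stayed called (camera adjusted p = 0.00175). TNC, which encodes tenascin C, a glycoprotein of remodelling tissue, rose 5.74-fold, from 9.11 ± 0.18 to 11.64 ± 0.15, with 2.52 and 2.62 from its probes. FN1, which encodes fibronectin, rose 2.27-fold, TGFBI 2.03-fold and LTBP1, which binds latent TGF-beta, 2.07-fold. SPARC, chosen after its value was seen, fell by 0.86.

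The contractile and myofibroblast list had 9 of 22 members higher and none lower, with 13 not passing (12 higher adjusted over the list alone). Its median was 0.41, with an adjusted p of 0.000393 (adjusted p = 0.337 with an estimated correlation). Leaving out Syy replicate 3 and control replicate 2 gave 5 higher members and a median of 0.31, with the list still called (camera adjusted p = 0.00175). TPM1, a tropomyosin, rose 2.12-fold, MYH9, the heavy chain of non-muscle myosin, 2.58-fold, and ACTN1, an actin crosslinker, 1.85-fold. ACTA2, smooth muscle actin and the usual mark of activated stellate cells, rose by 0.54 ± 0.08 (SE). Its call was lost with the replicate block (adjusted p = 0.0509) and without Syy replicate 3 and control replicate 2 (0.0923, in a range of 0.00483 to 0.0923 over the alternatives). ACTG2 rose by 0.73. The coding sequences of ACTA2 and ACTG2 are similar, so a probe of one might read the other. Probe sequences were not used here, so this was not checked and both values are uncertain. VIM rose by 0.53, a call lost after median centring (adjusted p = 0.0765, in a range of 0.00124 to 0.0765 over the alternatives). DES, at the floor of the array in both groups, read -0.03 and was not called.

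TGF-beta signalling and its direct targets had 10 of 24 members higher and none lower (13 and 3 adjusted over the list alone), with a median of 0.21 and an adjusted p of 0.0124 (adjusted p = 0.38 with an estimated correlation; 0.08, with 7 higher and 2 lower, among probes above the median). It had 5 higher members without control replicate 1, 6 without control replicate 2 or 3, and 2 without Syy replicate 3 and control replicate 2. Without that pair of arrays the list stayed called (camera adjusted p = 0.0159). CTGF, a secreted target of TGF-beta and YAP, rose 2.16-fold and ENG, a co-receptor, 1.56-fold. PMEPA1, from a probe near the floor, read 13.75 ± 1.25 in deposited intensity in controls and 29.71 ± 2.84 with Syy (SD, n = 3 each). Its log2 fold change ran from 0.261 to 0.865 over the alternatives. TGFB1 itself was not called (0.22, adjusted p = 0.385), nor were the stellate cell genes TIMP1 (-0.18, adjusted p = 0.149) and MMP2 (0.49, adjusted p = 0.0579; 0.0162 after median centring and 0.0295 among probes above the median, in a range of 0.0162 to 0.159 over the alternatives). The list of PDGF and growth factor signalling had 9 of 23 members higher and 1 lower (13 and 2 adjusted over the list alone), with a median of 0.38 and an adjusted p of 0.00451 (adjusted p = 0.375 with an estimated correlation). In this list 13 were higher after median centring, 6 without control replicate 1 and 1 without Syy replicate 3 and control replicate 2. Without that pair of arrays the list stayed called, with a median of 0.29 (camera adjusted p = 0.00518). EDN1, the precursor of endothelin 1, rose 2.43-fold, and IGFBP3 and IGFBP5, which bind insulin-like growth factors, rose 2.34-fold each, with a log2 fold change of IGFBP5 from 0.766 to 1.458 over the alternatives. IGF1R rose 1.63-fold on its brightest probe, a call lost with the mean over its probes (adjusted p = 0.391, in a range of 0.0018 to 0.391). PDGFRB, the PDGF receptor of stellate cells, read 0.42 higher without passing (adjusted p = 0.0664; 0.0453 without Syy replicate 3, 0.0115 after median centring and 0.037 with the replicate block, in a range of 0.0115 to 0.174 over the alternatives).

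Of the 29 measured genes of the oxidative stress list, 13 fell, none rose and 16 did not pass (13 lower and 1 higher adjusted over the list alone). The list holds targets of the transcription factor NRF2. It also holds NFE2L2, which encodes NRF2 itself, and KEAP1, the inhibitor of NRF2, both counted among the 13. The median log2 fold change was -0.21, the mean -0.69 and the adjusted p 1.9e-05 (adjusted p = 0.316 with an estimated correlation). HMOX1, which encodes the haem-degrading enzyme haem oxygenase 1, was 8.74-fold lower, at 9.63 ± 0.26 with Syy and 12.76 ± 0.11 in controls. SLC7A11, the cystine transporter that feeds glutathione synthesis, was 6.37-fold lower; its second probe lay at the floor in both groups, and the log2 fold change of the gene ran from -3.107 to -1.38 over the alternatives. OSGIN1 was 3.40-fold lower and AKR1C1, an aldo-keto reductase, 2.56-fold lower; close relatives of AKR1C1 can share its probe, so its value is uncertain. Genes chosen after their values were seen were GCLM, for a subunit of glutathione synthesis (-1.60), TXNRD1 (-1.45), NFE2L2 (-0.52) and KEAP1 (-0.60), all called. SRXN1 (-0.05, adjusted p = 0.694), NQO1 (0.04, adjusted p = 0.676) and GSR (0.08, adjusted p = 0.703), chosen the same way, were not called. AKR1B10, another member chosen after its values were seen, varied between arrays. It read 8.11, 9.54 and 5.29 in the controls and 4.60 to 6.76 with Syy, and was not called (adjusted p = 0.247). In the values as deposited 11 members fell and 1 rose. Without Syy replicate 3 and control replicate 2 the list had 9 lower members and stayed called (camera adjusted p = 0.00122).

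**Figure D2:**
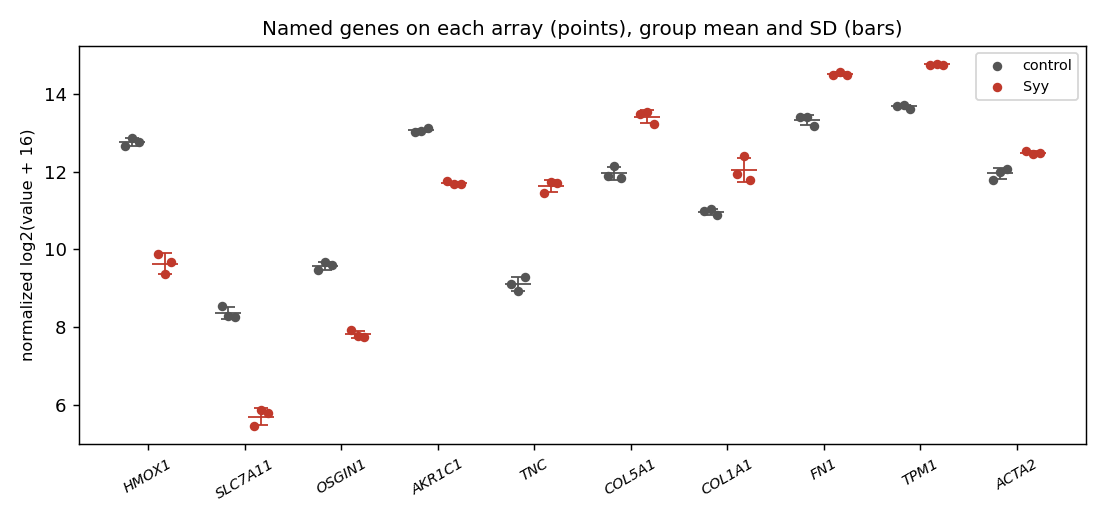
Normalized log2(value + 16) levels of 10 named genes, with 3 control (grey) and 3 Syy (red) arrays as points and bars for the group mean and SD. HMOX1 lies at 12.76 in controls and 9.63 with Syy, and TNC at 9.11 and 11.64.

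Of the 47 genes of G1/S and DNA replication, 18 rose, 4 fell and 25 did not pass (22 and 4 adjusted over the list alone), with a median of 0.25 and an adjusted p of 0.000393 (adjusted p = 0.317 with an estimated correlation). The values as deposited gave 26 higher and 1 lower. The list had 8 higher members without Syy replicate 3 and control replicate 2, and stayed called (camera adjusted p = 0.00975). UHRF1, which maintains DNA methylation, rose 2.07-fold, the helicase subunits MCM4 and MCM3 2.01-fold and 1.85-fold, and RRM2, a subunit of ribonucleotide reductase, 1.80-fold. A second bright probe of RRM2 read 0.18 and was not called, and the change of RRM2 ran from 0.515 to 0.921 over the alternatives. In oxidative phosphorylation 13 of 52 members fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.14 and an adjusted p of 0.00511 (adjusted p = 0.317 with an estimated correlation). The number of lower members was 7 without Syy replicate 2, 8 without Syy replicate 3, 4 without control replicate 1 or 3, 5 without control replicate 2 and 3 with the replicate block. The values as deposited gave 7 lower and 4 higher. Without Syy replicate 3 and control replicate 2 none fell and 1 rose. The list as a whole stayed called in that fit, with a median of -0.20 (camera adjusted p = 0.00518). UQCRB fell by 0.98 (0.519 to 1.107 over the alternatives). NDUFC2 fell by 0.47, a call lost after median centring and in the values as deposited (adjusted p = 0.0776 and 0.258, in a range of 0.00894 to 0.258). NDUFA2 fell by 0.37, a call lost with the replicate block (adjusted p = 0.0508) and without Syy replicate 3 and control replicate 2 (0.0758, in a range of 0.00462 to 0.0758). The second bright probe of NDUFA2 read -0.26 and was not called (adjusted p = 0.0525). ATP5B, a subunit of ATP synthase, went the other way and rose by 0.39. That call was lost after median centring and with the replicate block (adjusted p = 0.306 and 0.0631, in a range of 0.00523 to 0.306). The second bright probe of ATP5B read 0.18 and was not called (adjusted p = 0.226).

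Of 39 interferon-stimulated genes, 15 fell and 2 rose (18 and 5 adjusted over the list alone), with a median of -0.15 and an adjusted p of 0.0124 (adjusted p = 0.401 with an estimated correlation). ISG15, a ubiquitin-like protein, was 2.24-fold lower, IFIT1 1.96-fold lower (log2 fold change from -1.573 to -0.698 over the alternatives) and IFITM1 1.56-fold lower. IFI44, from a probe near the floor, read 37.3 ± 6.65 in deposited intensity in controls and 13.4 ± 2.46 with Syy (SD, n = 3 each). Its log2 fold change ran from -1.637 to -0.534 over the alternatives. The members that rose, STAT2 and MX2, were chosen after their values were seen. In the values as deposited 6 members fell and 3 rose. Lower members numbered 8 without Syy replicate 2 or control replicate 2, 7 without control replicate 3 and 5 with the replicate block. Without Syy replicate 3 and control replicate 2 they numbered 3, and the list stayed called (camera adjusted p = 0.0243).

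The lists of YAP and TEAD targets, focal adhesion and fatty acid synthesis were called only narrowly. Of 20 targets of YAP and TEAD, 7 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.15 and an adjusted p of 0.0305 (adjusted p = 0.329 with an estimated correlation). The receptor kinase AXL rose 1.81-fold, ARHGEF17 1.80-fold and NUAK2 1.49-fold. Of 29 focal adhesion and integrin genes, 9 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.20 and an adjusted p of 0.0479 (adjusted p = 0.375 with an estimated correlation). TNS1 rose 2.55-fold, TNS3 1.79-fold, PXN, which encodes paxillin, 1.58-fold and CD44 1.51-fold. Over the alternatives the log2 fold change of TNS3 ran from 0.432 to 1.099 and that of CD44 from 0.296 to 0.885. In fatty acid synthesis 7 of 21 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.23 and an adjusted p of 0.0445 (adjusted p = 0.403 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, rose 1.97-fold. ACACB, from a dim probe, read 27.48 ± 3.78 in deposited intensity in controls and 54.35 ± 3.10 with Syy (SD, n = 3 each). Its log2 fold change ran from 0.326 to 0.735 over the alternatives. FASN, the fatty acid synthase, rose by 0.59 on the log2 scale, a call lost with the replicate block (adjusted p = 0.0524, in a range of 0.00303 to 0.0582). ELOVL5, an elongase, was 2.01-fold lower on one probe, while its other bright probe read 0.11 and was not called. The change of ELOVL5 ran from -1.15 to -0.447 over the alternatives. Without Syy replicate 3 the adjusted p values of these lists were 0.104, 0.082 and 0.117, and without control replicate 1 they were 0.0617, 0.0791 and 0.0839. The first pair of lists also lost their calls without Syy replicate 1 (adjusted p = 0.0977 and 0.0739), and the focal adhesion list without control replicate 3 (adjusted p = 0.0992). All 3 lost them among probes above the median (adjusted p = 0.0769, 0.0681 and 0.0866), with array weights (0.0545, 0.0545 and 0.0573) and without Syy replicate 3 and control replicate 2 (0.0556, 0.0698 and 0.0552). Without that pair of arrays 5, 2 and 1 members of the lists rose and 0, 1 and 1 fell. Members of the fatty acid list that rose numbered 4 without Syy replicate 1 and 3 with the replicate block. Focal adhesion members that rose numbered 6 without Syy replicate 1, without control replicate 2 or with the replicate block. The fatty acid list lost its call with the replicate block (0.058) and among probes above the 25th percentile (0.0501). The focal adhesion list lost its call with a pseudocount of 50 and with a pseudocount of 1 and values below 0 set to 0 (0.0512 each).

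**Figure D3:**
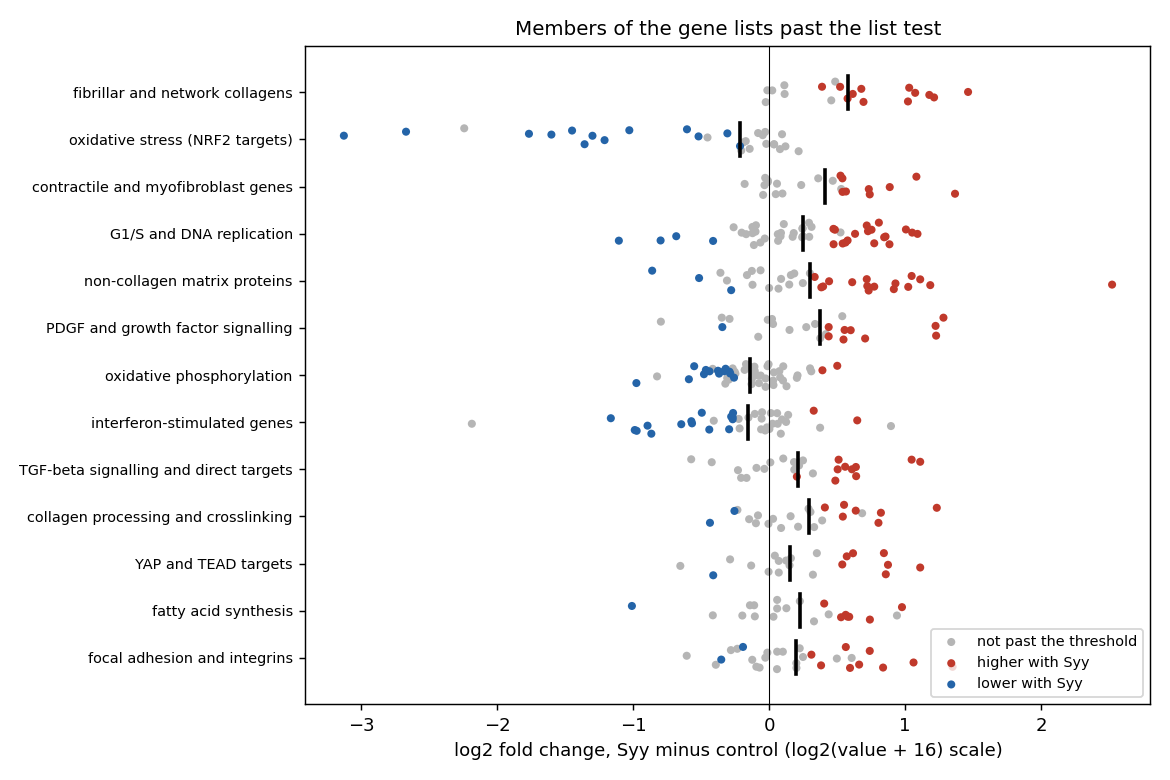
Log2 fold change, Syy minus control, of every measured member of the 13 called lists, 1 point per gene, coloured by its own call; black bars are list medians. The medians run from -0.21 for oxidative stress genes to 0.58 for collagens.

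The lists of the secretory pathway, the process named in the submitters' description of Syy, were not called by camera with the preset correlation, whereas fry called COPII, COPI and Golgi transport (adjusted p = 0.00893) and ESCRT and extracellular vesicle genes (adjusted p = 0.0285). COPII, COPI and Golgi transport had 12 of 37 members higher and 6 lower (14 and 6 adjusted over the list alone; median 0.15, camera adjusted p = 0.0755). Camera called this list after median centring (adjusted p = 0.00845), with the mean over all probes of a gene (0.029) and without control replicate 2 (0.0262) or 3 (0.041), but not with an estimated correlation (0.401). With that correlation the ESCRT list had an adjusted p of 0.403. Exocytosis and SNARE genes had 6 higher and 6 lower of 45 (adjusted p = 0.699), ESCRT and extracellular vesicle genes 2 and 4 of 29 (adjusted p = 0.287), signal peptide and translocon genes 6 and 5 of 29 (adjusted p = 0.754) and the unfolded protein response 6 and 5 of 33 (adjusted p = 0.921). Adjusted over the list alone, those 4 lists had 6 and 7, 2 and 4, 6 and 9, and 6 and 5. These counts changed with the scaling and when single arrays were left out. In the values as deposited the COPII list had 15 higher and 0 lower, exocytosis 7 and 2, ESCRT 2 and 1, signal peptide genes 6 and 1 and the unfolded protein response 10 and 3. Without control replicate 1 these lists had 8 and 2, 5 and 3, 1 and 3, 5 and 2, and 3 and 1. Over all genes that fit, with fewer arrays, called 1205 higher and 1153 lower instead of 2017 and 2104. Single members passed: the small GTPases ARF1 and ARF3 rose 1.57-fold and 1.67-fold, and the exocyst subunit EXOC4 rose 1.53-fold. RPN2 and SRP68, of the signal peptide and translocon list, rose 2.26-fold and 2.07-fold. VAMP7, a vesicle SNARE, was 1.99-fold lower and DNAJB9, a chaperone of the endoplasmic reticulum read by a dim probe, 2.33-fold lower (log2 fold change from -1.782 to -0.731 over the alternatives), while its fellow chaperone HYOU1 rose 1.78-fold. PDCD6IP, from a probe near the floor, read 24.06 ± 6.45 in deposited intensity in controls and 10.7 ± 1.67 with Syy (SD, n = 3 each). Its log2 fold change ran from -1.286 to -0.336 over the alternatives. CHMP4B rose 1.33-fold, a call lost after median centring and with the mean over its probes (adjusted p = 0.0904 and 0.294, in a range of 0.0041 to 0.294).

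The largest changes of single genes came mostly from probes near background in 1 group, where the size of the change depends on the pseudocount; mean deposited intensities are given for these (SD, n = 3 each). TCTN3, a protein of the primary cilium, read 0.70 ± 0.61 in controls and 166.4 ± 11.97 with Syy, and its log2 fold change ran from 1.99 to 6.58 over the alternatives. SH2D4A, C22orf46, CSPG4, MAN2C1, SNRPD3 and UBE4B, each with a single probe, read 1.71 to 12.3 in controls and 104.9 to 161.8 with Syy. ADAR, the RNA-editing enzyme, read 16.8 ± 24.9 in controls and 173.2 ± 39.8 with Syy but lost its call without Syy replicate 2, control replicate 2 or control replicate 3 (adjusted p = 0.0574, 0.0624 and 0.0525, in a range of 0.00392 to 0.147) and, as did KRTAP4-12, with the replicate block (adjusted p = 0.0571). H6PD, at 30.8 ± 26.0 and 191.0 ± 31.2, had a second probe that changed the same way by 1.37, and lost its call without Syy replicate 1 or control replicate 2 (adjusted p = 0.0616 and 0.0611, in a range of 0.00441 to 0.134). C10orf10 fell from 201.5 in controls to 6.26 with Syy, with a log2 fold change from -5.81 to -2.31 over the alternatives, and NFKBIL1 fell from 147.5 to 1.72. DYNLT3, HBD and GRAMD1C read 98.6 to 126.7 in controls and 5.75 to 10.5 with Syy. PIR read 185.2 ± 37.1 and 30.5 ± 19.5. KRTAP4-12, at 116.0 ± 8.8 and 15.9 ± 22.2, and KIAA1841, at 124.1 ± 44.0 and 22.3 ± 24.9, lost their calls without any 1 control, with adjusted p from 0.0512 to 0.0784; the call of KIAA1841 was also lost without Syy replicate 2 (adjusted p = 0.0725), and its other probes were not called.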

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

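Probes with no listed gene took no part in the gene comparison. Tested with all 31741 probes, 288 of them were higher and 291 lower with Syy at an adjusted p under 0.05 (limma); no explanation was tested.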

How the results depend on the processing

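Over the alternatives, most named genes kept direction and side of the threshold: of their values in 87 genes, 1392 were alike, 64 no longer passed, 14 newly passed and 4 reversed. All 4 were DES, at the floor: 0.025 in the values as deposited, 0.003 without the 2 doubted arrays, and -0.077 to 0.018 with single samples left out (above 0 without Syy replicate 3, 0.002, and control replicate 3, 0.018), against -0.029. The values as deposited gave 3157 higher and 737 lower genes, and leaving out the 2 doubted arrays gave 566 and 535, with fewer samples and 1007 genes shared in direction with the calls over 6 arrays; both were chosen after seeing the data. Genes changed at least 2-fold numbered 174 with a pseudocount of 50 and 550 with a pseudocount of 1 and values below 0 set to 0 together (added after seeing the data). Leaving out each sample in turn gave 1205 to 1786 higher genes, 1079 to 1966 lower and 238 to 373 changed 2-fold, with 7 to 12 lists higher and 3 to 4 lower. With an estimated correlation, a camera test of little power with 6 arrays, 0 lists were called higher and 0 lower, at a lowest adjusted p of 0.316. Camera with the preset correlation called 10 and 3 and fry 17 and 6, all 13 among them. Probes above the median left 6 lists higher, and the mean over all probes of a gene gave 5 lists lower. Apart from these, the cause was not tested.

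The replicate block gave 1051 higher and 852 lower genes. Samples of one number did not deviate together: the correlations of their deviations were -0.08, -0.08 and -0.03, and 0 of the 3 Syy samples correlated best with the control of their own number. Dim probes limit the arrays: the median of all probes was 5.29 on the log2 scale, close to the pseudocount's own level.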

Other observations

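A pair of gene families was chosen after the data were seen. Of 12 SNORD genes, which encode small nucleolar RNAs, 7 were lower and 0 higher, with a median of -0.62. Probe sequences were not used here, so whether these probes read the small nucleolar RNAs themselves or other transcripts was not checked. Of 289 olfactory receptor genes, which stellate cells are not known to use, 12 were higher and 8 lower, 6.9% against 22.4% of all genes. Among the lists not called by camera, apoptosis regulators had 2 members higher and 9 lower of 31 (adjusted p = 0.0873; 0.049 without Syy replicate 3, 0.00888 by fry and 0.337 with an estimated correlation), p53 targets 6 and 9 of 30 (adjusted p = 0.466), NF-kappaB feedback and target genes 4 and 8 of 20 (adjusted p = 0.392; 0.0211 by fry and 0.521 with an estimated correlation) and replication-dependent histones 3 and 7 of 30 (adjusted p = 0.0755; 0.00605 without Syy replicate 1, 0.032 with the replicate block and 0.029 with the mean over all probes of a gene, but 0.733 with an estimated correlation; median -0.13, and 0.02 in the values as deposited). Mitotic genes had 15 higher and 5 lower of 50 (adjusted p = 0.134). These counts changed with the scaling and when single arrays were left out, which also lowered the calls over all genes. In the values as deposited apoptosis regulators had 2 higher and 3 lower, p53 targets 7 and 2, NF-kappaB genes 6 and 5, histones 3 and 1 and mitotic genes 17 and 1. Without control replicate 1 they had 1 and 5, 4 and 5, 3 and 5, 1 and 2, and 10 and 2. Without control replicate 2 p53 targets had 4 and 3, and without Syy replicate 2 apoptosis regulators had 0 and 4 and histones 2 and 2. Cytosolic ribosomal proteins had 3 higher and 7 lower of 57 (camera adjusted p = 0.134). Camera called that list after median centring (3.44e-05), with the mean over all probes (0.0205) and as deposited (1.1e-05, 4 higher and 1 lower). With an estimated correlation it did not (0.521). Wnt, Notch and Hedgehog targets had 4 and 0 of 22 (0.0755), and 0.0404 without Syy replicate 1, 0.0243 without the 2 doubted arrays and 0.337 with an estimated correlation. Markers of cholangiocytes, macrophages, lymphocytes and endothelium had 2, 1, 0 and 0 members higher and 0, 0, 1 and 1 lower.

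Of the tests below, those of an effect of Syy on hepatocyte transcripts, of normalization as the whole cause and of unequal probe spots were chosen only after the result was seen, as was the comparison of each bound with the spread over resampled genes. Syy replicate 3 held 59 genes at least 4-fold above both other Syy arrays, against 2 to 12 on the other arrays. In an effect of Syy the marker list would be higher in the other Syy arrays too, but its median there was 0.049 ± 0.046 (SD over resampled genes) above the controls, which argues against it. A swapped sample is argued against by 95.7% of the 3752 genes called without this array lying on the Syy side in it. RNA from hepatocyte-lineage cells stays open. A second list of 55 hepatocyte genes, written before its values were seen, had a median of 0.054 ± 0.064. That is under the 0.1 set beforehand as speaking against such RNA, but by less than its spread. Of the 55, 12 were over 1 log2 unit higher there and 0 on any other array. For Syy replicates 1 and 2 the reference included Syy replicate 3, so a rise there could hardly show. The median of Syy replicate 3 lay at the 99.75th percentile of 10000 random lists of matched level. The deposited intensity of ALB, usually among the most abundant hepatocyte transcripts, was 110.6 on that array and that of APOA2 16840, though levels of different probes cannot be set against each other.

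The fall of the oxidative stress genes was weighed next. Lower activity of NRF2 with Syy is a candidate explanation: a second list of 27 NRF2 targets, written before its values were seen, had a median log2 fold change of -0.259 ± 0.092 (SD over resampled genes), with 8 genes lower and 2 higher (camera p = 0.00271 with the preset correlation and 0.0876 with an estimated one). Foreign RNA in 2 arrays, whose presence is itself open, was weighed by leaving out Syy replicate 3 and control replicate 2. The median of the genes that fell was then -1.192, against -1.299 over 6 arrays. Those genes were picked by their fall over all 6 arrays, which favours that outcome, so it is no separate test. The whole list, fixed beforehand, had a median of -0.23 without the 2 arrays (camera adjusted p = 0.00122) and -0.21 with them. That argues against foreign RNA in these arrays as the whole cause. Normalization between arrays as the whole cause is argued against as well. The median difference between the groups in the values as deposited ran from -0.05 to 0.30 over the levels. That is small beside the -1.299 of the genes that fell, whose fall could thus hardly have halved. Their median of -1.1 ± 0.253 in the values as deposited is therefore no separate test. There 11 of the 13 were called lower, a number between the bounds set beforehand for a part in the calls. The list had a median of -0.21 there (camera adjusted p = 4.72e-07), while lower calls over all genes went from 2104 to 737. In the first list 16 of 29 members did not pass, NQO1 among them, so a fall of the whole class was not shown. Activity of NRF2 was not measured, and the hypothesis was formed on the same data.

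A set of 20 probes changed by at least 2 on the log2 scale with 1 group's mean under 5, close to the floor; 11 of them were higher and 9 lower. Without Syy replicate 3 and control replicate 2, 19 of the 20 kept such a change, so those 19 changes did not rest on these arrays alone. The probes were picked by their change over all 6 arrays, which favours that outcome, so it is no separate test of foreign RNA. A failed or unequal probe spot stays open: over the 5 genes with another bright probe, that probe's change in the first one's direction had a median of 0.924 ± 0.26, between the bounds set. Probes that switched between under 5 and over 6.5 numbered 27 to 36 between control arrays, 46 to 98 between Syy arrays and 67 to 120 between the groups. An effect of Syy on these genes was not tested apart from the comparison itself.

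The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes Syy and control arrays. A difference between the groups, whatever its origin, then widens the spread of that split and lowers its counts. The counts of the other splits are thus no measure of what would be called without a difference. The real split gave 2017 higher genes and the highest other split 1; 2104 lower and 0; 300 changed at least 2-fold and 1. For gene lists the real split gave 10 higher and the highest other split 6, so that 1 split of the 10, the real one, gave as many; it gave 3 lower and the highest other split 3, so that 2 of the 10 did.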
